A study of Mus musculus with 28 samples.

How the data were processed

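RNA sequencing was made from 28 libraries of mice carrying the Lgr5-GFP reporter, in which green fluorescent protein marks cells that express the stem cell receptor gene Lgr5. Cells of the small intestine had been sorted into an Lgr5-high and an Lgr5-low population, from animals on a control diet or on a diet with added cystine, the oxidised dimer of the amino acid cysteine. This gives 4 groups of 7 libraries. Per the labels' protocols, RNA was extracted with TRIzol and a column kit, and poly(A)-selected libraries were made with a kit that keeps strand information. The labels' extraction protocol names organoids as the RNA source, whereas the series' design text speaks of populations isolated from the small intestine, and the sources used here do not settle which applies. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries.

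The authors deposited 1 table of estimated counts per gene, given as whole numbers. Per the submitters' processing notes, transcripts were quantified with Salmon 1.3.0 and the genome build was mm10. The transcript annotation, the trimming and the summing of transcripts to genes are not given in the sources used here. Salmon shares reads among similar transcripts by a model, so values of near-identical genes (the alpha-defensins, Hspa1a and Hspa1b, Lyz1 and Lyz2) depend on how reads were divided. The table holds 54354 genes by Ensembl identifier. Of these, 51485 (94.7%) matched GENCODE M21 (GRCm38, the assembly also called mm10), which supplied the coordinates. Genes without a symbol numbered 1243 and held 0.00328% to 0.0111% of the counts of a library; they stayed in the tests.

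Total counts per library ranged from 2.75 to 21.5 M (mega). The common biological coefficient of variation was 0.629, so that single genes were measured with large errors even at 7 libraries per group. No pair of libraries within a group was alike within sampling noise: over 84 pairs, the chi-square statistic per gene ranged from 14.0 to 256. Levels are CPM, counts scaled to a common library size by TMM factors, and intervals and limits for low counts cover counting error only.

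Differences were tested with the quasi-likelihood method of edgeR 4.0.16 (robust fit, TMM factors, R 4.3.3) in 1 model with a mean per group over all 28 libraries. The filter filterByExpr left 12495 genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. The 5 contrasts were cystine against control in each population, the difference between these diet effects, and Lgr5-high against Lgr5-low on each diet. Every adjusted p given for a gene comes from this method unless another tool is named.

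Gene lists for cell types and pathways numbered 32 and were fixed before the data were examined, as were the contrasts, the tests and the rule for named genes. The 29 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, and again with a correlation estimated from the data. The lists for stromal and endothelial cells, erythrocytes and pancreatic acinar cells had 4, 3 and 1 tested genes and were not tested as lists. The rule named, for the diet contrasts and for the populations on control diet, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among genes past the threshold with a mean of at least 2 CPM. A direction with fewer such genes was filled to 5 with the genes of lowest p and at least the same mean, named as not passing. For the difference of diet effects, the rule took the 5 genes of lowest p in each direction, also with a mean of at least 2 CPM. It added 2 to 4 members of lowest p of each list described, and Lgr5, Il22 and Il22ra1. Predicted genes, and immunoglobulin and T cell receptor segments, were counted but not named by this rule. Results for a withheld item are not reported here.

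The sex of the animals is not given in the labels. Libraries were put in a female class when Xist exceeded 50 CPM and otherwise in a male class, and transcripts of the Y chromosome gave the same division. Control replicates 1 to 3 and cystine replicates 1 and 2 formed the male class in both populations. Results were recomputed within each class, a division chosen after the data had been seen.

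Other settings were DESeq2 1.42.0, limma-voom with sample quality weights, RLE size factors, no low-count filter, a filter of at least 1 CPM in at least 7 libraries, only the compared groups in the fit, and a term for the replicate number. Settings added after the data had been seen were a sex term, a term for a macrophage score, leaving out libraries under 5 M counts, and leaving out each library in turn. The macrophage score was the mean log2 CPM of 8 genes, Clec4f, Vsig4, Cd5l, Timd4, Marco, Folr2, C1qb and C1qc. Other splits of the libraries, 100 for genes and 75 for lists with the real one included, show how often chance groupings give as many calls.

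The procedure was tested on simulated counts with 200 changed genes, drawn from the means and library sizes of the real data. Changed genes were taken only among those with a mean of at least 2 CPM over all libraries, so the recovered shares do not cover lower genes. The male and female classes were not simulated. In the simulation of the diet effect in Lgr5-high, 26% of genes changed by a factor of 2 and 74% of those changed by a factor of 4 were recovered. In Lgr5-low the shares were 32% and 63%, for the difference of diet effects 5% and 43%, for the populations on control diet 30% and 77%, and on cystine diet 26% and 78%. False calls in these 5 simulations numbered 0, 3, 0, 3 and 6 in that order. In a simulation of 40 lists, all 5 that were shifted by a factor of 1.5 were recovered, with 0 false calls. Genes were drawn independently there, so the 0 false calls do not cover the correlated genes of real lists. In other splits of the real Lgr5-high libraries a median of 7 lists passed with the preset correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.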

Results

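The study profiled intestinal epithelium in mice given a control or a cystine diet, and its title ties dietary cysteine to stemness and to interleukin 22 from CD8 T cells. Sorted Lgr5-high cells, enriched for crypt stem cells, and Lgr5-low cells were sequenced in 7 libraries per population and diet, 28 in all. Depth differed between groups. Total counts, in M (mega, the unit used for depth throughout), averaged 14.8 ± 5.80 M (SD, n = 7) in Lgr5-high control libraries and 6.84 ± 4.40 M in Lgr5-high cystine libraries, a log2 difference of -1.21 (two-sided exact permutation test, p = 0.0227). In Lgr5-low cells the totals averaged 8.53 ± 5.3 M on control diet and 13.6 ± 6.24 M on cystine diet (log2 difference 0.70, exact permutation p = 0.150). Mitochondrially encoded transcripts made up 19.1% ± 3.16 and 20.3% ± 3.18 of counts in Lgr5-high control and cystine libraries, and 16.9% ± 1.5 and 15.5% ± 1.71 in the Lgr5-low groups. On cystine diet this share was 4.78 percentage points higher in Lgr5-high cells (exact permutation p = 0.00524, 1 of 4 such tests).

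The first comparison asked how the sorted populations differed on control diet. Lgr5-high cells carried the stem cell programme: Lgr5 itself, on chromosome 10 (115450311 to 115587780, GRCm38), stood at 35.0 ± 9.06 CPM (SD, n = 7) against 4.19 ± 3.61 in Lgr5-low cells, a log2 fold change of 2.99 ± 0.43 (SE, adjusted p = 9.85e-05). Olfm4, a secreted glycoprotein of crypt base cells, measured 4772 ± 1169 against 1210 ± 585 CPM (log2 fold change 1.98, adjusted p = 1.35e-05). In both genes all 7 Lgr5-high libraries lay above all 7 Lgr5-low libraries. Lgr5-low cells were richer in transcripts of goblet and enteroendocrine cells. Fcgbp, a protein of goblet cell mucus, measured 997 ± 380 against 232 ± 85.5 CPM (log2 fold change -2.11, adjusted p = 0.00161). Gip, an incretin hormone, measured 302 ± 146 against 63.5 ± 36.0 CPM (-2.25, adjusted p = 0.00664), with 7 of 7 Lgr5-high libraries below the Lgr5-low median.

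Among the lists, that of intestinal stem cells had 23 tested members, all with positive log2 fold changes (median 1.20). Of these, 10 passed over all genes and 21 when adjusted over the list alone (camera adjusted p = 2.29e-29, and 0.00169 with an estimated correlation). They included Ascl2, a transcription factor of stem cells (31.2 ± 10 against 8.68 ± 4.88 CPM, log2 fold change 1.86, adjusted p = 0.00105). Another was Slc12a2, a sodium, potassium and chloride cotransporter (329 ± 64.3 against 139 ± 45.4 CPM, 1.25, adjusted p = 0.000871). The Wnt target list was higher as well, with 4 of 14 members past the threshold over all genes and 7 adjusted over the list alone (median 1.20, adjusted p = 0.00260 with an estimated correlation). Its members Myc, a growth regulator (1.22, adjusted p = 0.00533), and Rnf43, a ubiquitin ligase that dampens Wnt receptors (0.95, adjusted p = 0.0395), were higher in Lgr5-high cells. Rnf43 no longer passed with only the compared groups in the fit (adjusted p = 0.0877). Enteroendocrine genes formed the list with the lowest median, -1.84, and 8 of 22 members passed over all genes and 15 adjusted over the list alone (adjusted p = 5.66e-05 with an estimated correlation). Among them were the hormones ghrelin, from Ghrl (19.8 ± 10.5 against 67.5 ± 37.7 CPM, -1.77, adjusted p = 0.00185), somatostatin, from Sst (5.71 ± 3.33 against 29.5 ± 11.5 CPM, -2.39, adjusted p = 0.00367). The tachykinin precursor Tac1 was also lower (-1.91, adjusted p = 0.00194). The granule protein Chgb was lower too (-1.60, adjusted p = 0.00297). In the goblet cell list 8 of 16 members passed over all genes and 13 adjusted over the list alone (median -1.35, adjusted p = 0.00200 with an estimated correlation). They included Agr2, a disulfide isomerase needed for mucin folding (687 ± 231 against 1974 ± 955 CPM, -1.52, adjusted p = 0.000608), and the transcription factor Creb3l4 (-1.34, adjusted p = 0.00297).

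Metabolic lists differed too. Sterol synthesis genes were lower in Lgr5-high cells in all 20 members (median -0.80), with 3 past the threshold over all genes and 7 adjusted over the list alone (adjusted p = 0.00354 with an estimated correlation). Among them were Msmo1 (-0.90, adjusted p = 0.0252) and Lss (-1.37, adjusted p = 0.0274), enzymes of the late cholesterol pathway. Lss and Msmo1 did not pass with only the compared groups in the fit (adjusted p = 0.0598 and 0.0866). The unfolded protein response list was lower (median -0.51, adjusted p = 0.0309 with an estimated correlation). Of its 15 members 1, the secreted chaperone-like factor Manf (-0.81, adjusted p = 0.0223), passed over all genes and 9 adjusted over the list alone. Nuclear-encoded oxidative phosphorylation genes were also lower (median -0.34, adjusted p = 0.0284 with an estimated correlation), with 0 of 19 members past the threshold over all genes in edgeR and 6 adjusted over the list alone. Uqcrfs1, a complex III subunit, stood at 73.1 ± 8.95 against 115 ± 22.6 CPM. A further 7 lists passed with the preset correlation only. Enterocyte, tuft cell, interleukin 22 and STAT3 response, and glutathione and NRF2 genes were lower, with adjusted p = 0.396, 0.119, 0.344 and 0.114 with an estimated correlation. Paneth cell, mitochondrially encoded and ribosomal protein genes were higher, with adjusted p = 0.822, 0.396 and 0.610 with an estimated correlation.

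In total 225 of 12495 genes passed, 98 higher and 127 lower in Lgr5-high cells. The largest positive log2 fold changes among named genes belonged to Vav3, a guanine nucleotide exchange factor (5.35 ± 0.85), Sorcs2, a sorting receptor (3.3 ± 0.58), Fstl1, a secreted glycoprotein (3.10 ± 0.70), Rgcc (2.60 ± 0.42), Cabcoco1 (2.50 ± 0.37), the Wnt antagonist Sfrp5 (2.25 ± 0.49), the receptor phosphatase Ptpro (2.13 ± 0.52) and Agr3 (1.99 ± 0.27), with SE after each value. The most negative belonged to Fer1l6 (-4.18 ± 1.0), the prohormone-processing enzyme Cpe (-2.92 ± 0.69), Mptx1 (-2.78 ± 0.64), the hormone cholecystokinin, from Cck (-2.54 ± 0.63), Hmgn3 (-2.21 ± 0.54), Rgs2 (-2.20 ± 0.48) and the nucleoside transporter Slc28a3 (-2.16 ± 0.58). Without libraries under 5 M counts, Rnf43, Fstl1, Sfrp5, Cpe, Hmgn3 and Slc28a3 no longer passed. Within the female class (4 against 4 libraries) 730 genes passed and within the male class (3 against 3) 24, and the log2 fold change of Lgr5 was 2.56 ± 0.39 and 4.26 ± 0.75 (SE). The count was 410 with DESeq2, 781 with limma-voom, 450 with a sex term, 144 with no low-count filter and 131 with only the compared groups in the fit. Without Lgr5-high control replicates 3, 4 or 5 it was 147, 140 or 123, and without Lgr5-low control replicates 3 or 6 it was 464 or 144.

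**Figure D1:**
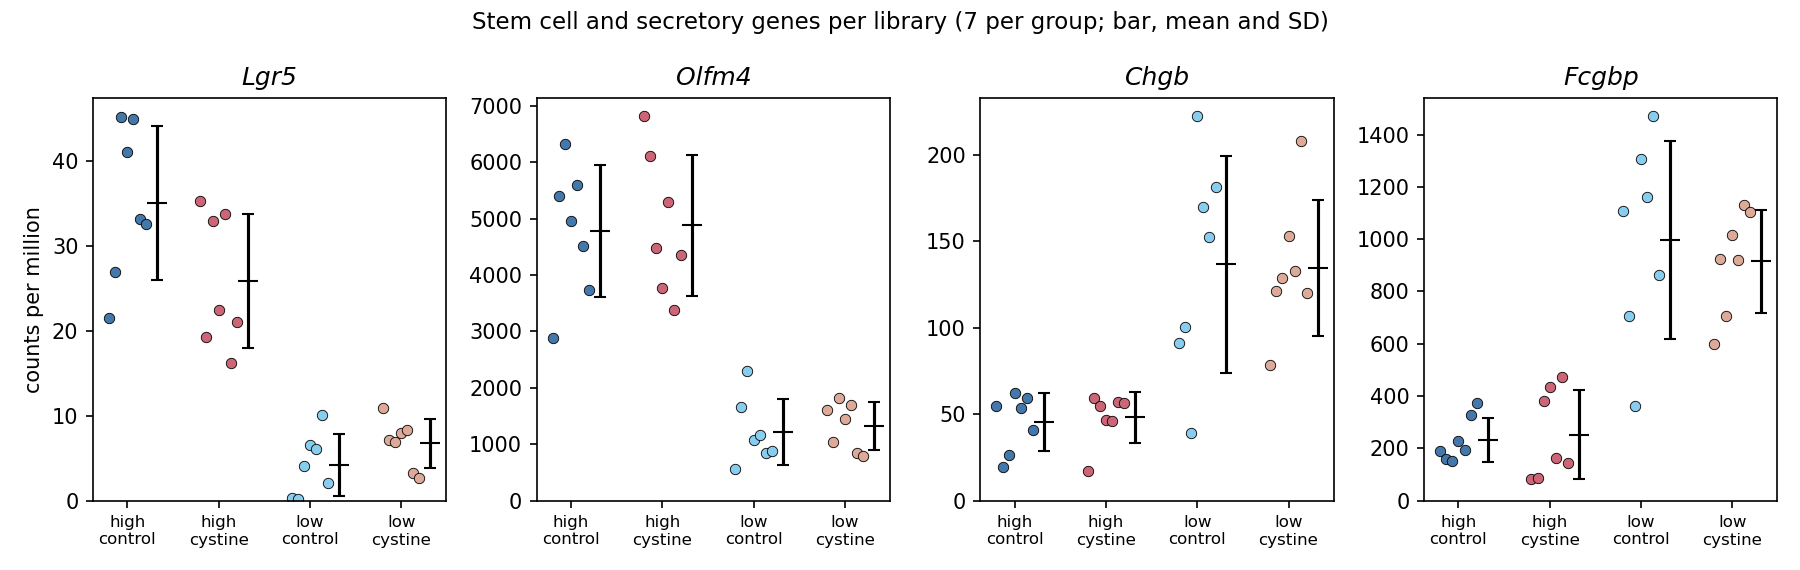
Levels in CPM (linear axis) of Lgr5, Olfm4, Chgb and Fcgbp in each of the 28 libraries, with the mean and SD of the 7 libraries of a group as a bar. On control diet Lgr5 averaged 35.0 CPM in Lgr5-high and 4.19 CPM in Lgr5-low cells, and Fcgbp 232 and 997 CPM.

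The same comparison on cystine diet, in other libraries, gave 330 genes, 138 higher and 192 lower in Lgr5-high cells. Stem cell genes were again higher: Lgr5 measured 25.8 ± 7.89 against 6.76 ± 2.89 CPM (SD, n = 7; log2 fold change 1.96, adjusted p = 0.00614) and Olfm4 4883 ± 1251 against 1315 ± 423 CPM (1.89, adjusted p = 1.86e-05). Goblet and enteroendocrine genes were again lower, Fcgbp at 252 ± 170 against 915 ± 198 CPM (-1.86, adjusted p = 0.00330) and Gip at 64.0 ± 39.5 against 261 ± 102 CPM (-2.03, adjusted p = 0.0113). Calls shared with the control diet numbered 36 higher and 64 lower genes, where independent lists would share 1.08 and 1.95, and 0 genes were called in opposite directions. Myeloid genes were higher in Lgr5-high cells on this diet, with 8 of 10 tested members past the threshold over all genes and 9 adjusted over the list alone (median 2.38, adjusted p = 0.0204 with an estimated correlation). Among them were Fcer1g (2.3, adjusted p = 0.00147), Cd68 (2.24, adjusted p = 0.00286) and the complement gene C1qb (2.94, adjusted p = 0.00368).

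Of 29 lists 15 passed on cystine diet. With an estimated correlation 7 did: intestinal stem cell (adjusted p = 0.0108), Wnt target (0.0134) and myeloid genes were higher, and goblet cell (0.0108), enteroendocrine cell (0.00655), sterol synthesis (0.0134) and unfolded protein response genes (0.0182) were lower. The enterocyte, tuft cell, interleukin 22 and STAT3 response, glutathione and NRF2, and oxidative phosphorylation lists were lower with the preset correlation only, with adjusted p = 0.384, 0.0539, 0.229, 0.169 and 0.0983 with an estimated correlation. Paneth cell, mitochondrially encoded and ribosomal protein lists were higher with the preset correlation only (adjusted p = 0.715, 0.0983 and 0.452 with an estimated correlation). The gene count was 485 within the female class (5 against 5 libraries) and 104 within the male class (2 against 2), 585 with DESeq2, 880 with limma-voom and 619 with a sex term. It was 199 or 183 without Lgr5-low cystine replicates 6 or 7, and 183, 214 or 194 without Lgr5-high cystine replicates 2, 5 or 7.

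The comparison at the centre of the series asked what cystine changed in Lgr5-high cells. Transcripts of macrophages were higher on cystine, while stem cell genes were not shown to differ. Cd68, a lysosomal membrane protein of macrophages on chromosome 11 (69664213 to 69666153), measured 59.1 ± 34.7 CPM on cystine and 7.29 ± 2.57 on control diet (SD, n = 7; log2 fold change 3.02 ± 0.45 SE, adjusted p = 0.000596), with 6 of 7 cystine libraries above all 7 control libraries. Fcer1g, the common gamma chain of Fc receptors on chromosome 1 (171229572 to 171234365), measured 41.2 ± 23.6 against 5.19 ± 2.38 CPM (2.97 ± 0.43, adjusted p = 0.000402), with 7 of 7 libraries above. Lgr5 stood at 25.8 ± 7.89 against 35.0 ± 9.06 CPM (log2 fold change -0.44 ± 0.40, adjusted p = 1.0) and Olfm4 at 4883 ± 1251 against 4772 ± 1169 CPM (0.03 ± 0.24).

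In total 21 genes passed, 21 higher and 0 lower on cystine, and 535 genes had an unadjusted p under 0.05, where chance alone would give 625. Besides Cd68 and Fcer1g, the named genes were the secreted phospholipase Pla2g7 (log2 fold change 3.54 ± 0.73 SE, adjusted p = 0.0192), Wfdc17 (3.38 ± 0.65, 0.0226), Cd300c2 (3.37 ± 0.72, 0.0306). Further ones were the lipid-binding protein Fabp7 (3.3 ± 0.72, 0.0347), the complement receptor Vsig4 (3.20 ± 0.60, 0.00817), the signalling adaptor Tyrobp (3.08 ± 0.53, 0.00659), the folate receptor Folr2 (3.04 ± 0.53, 0.00558), the Fc receptor Fcgr3 (3.03 ± 0.68, 0.0442), Aif1 (3.02 ± 0.58, 0.0129) and C1qb (2.79 ± 0.59, 0.0240). Outside the naming rule, and chosen after their values were seen, Clec4f (70.0 ± 45.1 against 8.80 ± 2.61 CPM, 2.98, adjusted p = 0.0135) and Cd5l (34.7 ± 23.3 against 4.61 ± 2.10 CPM, 2.89, adjusted p = 0.0347), genes known from Kupffer cells of the liver, were among the 21. The dynein light chain gene Dynlt1b (385 ± 126 against 156 ± 28.5 CPM, 1.3, adjusted p = 0.00625), which has close copies, was not a macrophage marker. The lowest p among genes with negative values that the naming rule admits belonged to the elongation factor Eef2 (-0.62, adjusted p = 0.0991), Tm2d1 (-1.42, 0.101), Isoc1 (-0.83, 0.101), the aminopeptidase Xpnpep1 (-0.82, 0.115) and Garnl3 (-1.64, 0.146), and none of them passed in edgeR. With DESeq2, Eef2, Tm2d1, Isoc1 and Garnl3 passed (adjusted p = 0.0382, 0.0236, 0.0185 and 0.00204), and with limma-voom Eef2, Tm2d1 and Garnl3 (0.000749, 0.0142 and 0.0172).

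All 21 genes were also positive within the female class (5 cystine against 4 control libraries, median log2 fold change 3.39, 43 genes called, 34 higher and 9 lower) and within the male class (2 against 3, median 2.01, 38 genes called, 10 higher and 28 lower). The 21 genes had been chosen with the same libraries, so these signs are not independent support. Of the 2 male cystine libraries, replicate 2 held 257 CPM of 8 summed macrophage genes and replicate 1 held 6.18 CPM. The male value thus rests mainly on replicate 2. Without the libraries under 5 M counts, which left 4 cystine and 6 control Lgr5-high libraries, 0 genes passed in edgeR (577 with an unadjusted p under 0.05). The 21 genes were all positive, with a median of 2.23 in place of 2.99. The count was 89 with DESeq2, 38 with limma-voom, of which 10 were among the 21, 39 with only the compared groups in the fit, 41 with a sex term, and 1 (Alb, log2 fold change -1.57, named after its value was seen) with a term for a macrophage score. That score holds Clec4f, Vsig4, Cd5l, Folr2 and C1qb of the 21 genes, so the loss of these calls was in part built in. The count was 44 without Lgr5-high cystine replicate 1, the library with 6.18 CPM of 8 summed macrophage genes where the other 6 held 109 to 401 CPM. Without Lgr5-high control replicates 1, 3, 4, 5, 6 or 7 it was 13, 11, 9, 9, 9 or 7, and without cystine replicates 2, 3, 6 or 7 it was 11, 10, 10 or 9.

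**Figure D2:**
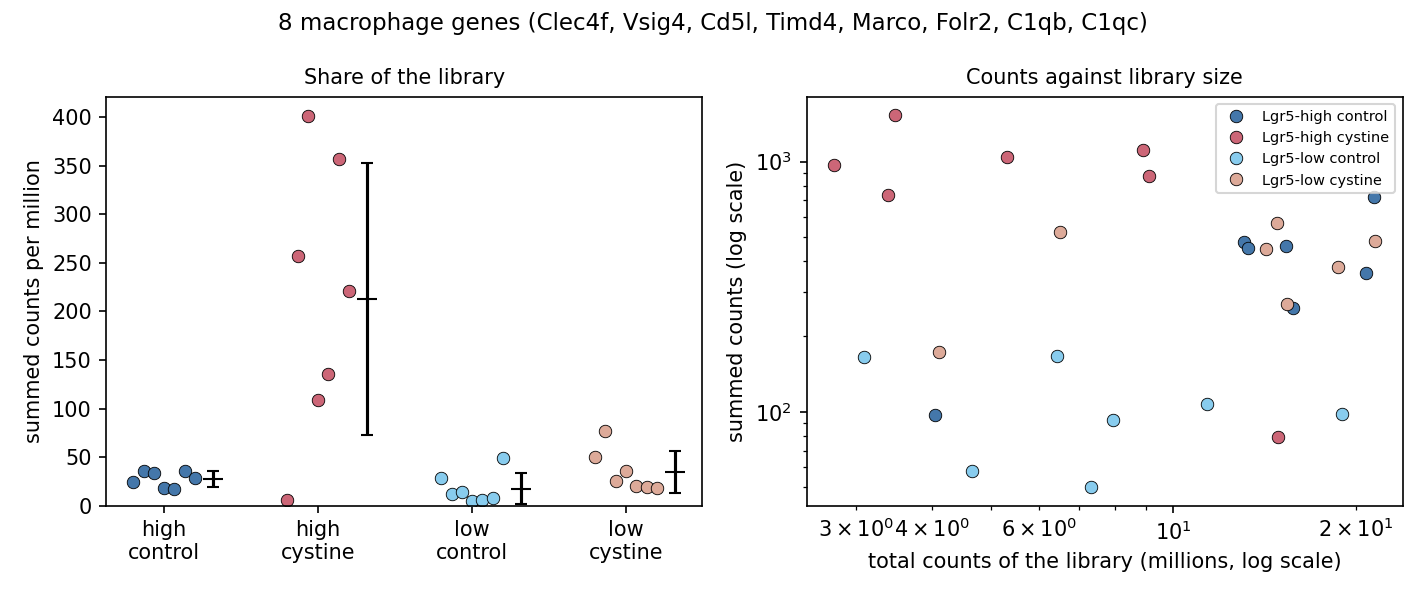
Left, summed CPM of 8 macrophage genes in each library, with the mean and SD of the 7 libraries of a group as a bar. Right, their summed counts against the total counts of the library, both axes on a log scale. Lgr5-high cystine libraries hold 109 to 401 CPM of these genes, except replicate 1, which holds 6.18 CPM.

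Of the lists, that of myeloid cells was higher on cystine, with all 10 tested members positive (median 2.75). Over all genes 5 passed and adjusted over the list alone 9 did (camera adjusted p = 1.17e-31, and 0.00234 with an estimated correlation). The dissociation stress list, immediate early and heat shock genes that respond to tissue handling, was higher as well (median 0.53, adjusted p = 1.26e-05, and 0.0380 with an estimated correlation). In edgeR 0 of its 16 members passed over all genes and 4 adjusted over the list alone. These 4 were the chaperones Hspa1b (1.90 ± 1.24 against 0.132 ± 0.142 CPM, log2 fold change 3.63) and Hspa1a (3.24 ± 3.11 against 0.272 ± 0.209 CPM, 3.50), the phosphatase Dusp1 (3.61 ± 2.87 against 0.488 ± 0.265 CPM, 2.81) and the transcription factor Atf3 (3.19 ± 1.73 against 0.464 ± 0.318 CPM, 2.69). Hspa1a, Hspa1b and Dusp1 passed over all genes with DESeq2 (adjusted p = 0.0255, 0.0255 and 0.0286). The stress list did not pass with a macrophage score term (adjusted p = 0.169), and its adjusted p was 0.000632 in the female and 0.0624 in the male class. Within the cystine Lgr5-high libraries its mean rose with that of the macrophage genes (Pearson r = 0.92, exact permutation p = 0.000198, adjusted 0.000794, and r = 0.90 without the 2 libraries farthest from the median). Spearman rho was 1 (exact p = 0.000397, adjusted 0.00159 over 4 groups). Both means were highest in replicate 3, followed by replicate 6, the shallowest of these libraries. They were lowest in replicate 1, the deepest, so depth cannot be told apart here.

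Enterocyte genes were lower on cystine with the preset correlation, in 24 of 25 members (median -0.42, adjusted p = 0.00545, but 0.973 with an estimated correlation), and 0 members passed adjusted over the list alone. Slc2a5, a fructose transporter, stood at 4.48 ± 3.34 against 12.5 ± 12.4 CPM and Vil1, an actin-binding protein of microvilli, at 118 ± 58.6 against 168 ± 43.4 CPM. Paneth cell genes were higher with the preset correlation (median 0.17, adjusted p = 0.0124, but 0.973 with an estimated correlation), with Mmp7, which processes defensins, at 236 ± 88.6 against 165 ± 94.5 CPM. T and innate lymphoid cell genes were higher (median 0.78, adjusted p = 0.0432, but 0.973 with an estimated correlation), and this call ended with RLE size factors (0.0679), a sex term (0.127) or without the libraries under 5 M counts (0.0546). Ptprc, the pan-leukocyte marker CD45, stood at 3.57 ± 3.03 against 0.951 ± 1.13 CPM.

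The lists nearest to the series' title did not pass in Lgr5-high cells. The intestinal stem cell list had a median log2 fold change of -0.11 (adjusted p = 0.911), with 0 of 23 members past the threshold over all genes and 0 adjusted over the list alone in edgeR. Ascl2 stood at 48.5 ± 15.3 against 31.2 ± 10 CPM (0.63 ± 0.31) and Cdca7 at 206 ± 37.1 against 250 ± 42.2 CPM. For the interleukin 22 and STAT3 response list the median was 0.10 (adjusted p = 0.658). Its acute-phase members Saa1 (2.33 ± 1.05 against 7.03 ± 4.31 CPM, -1.61) and Saa2 (-1.77) and its antimicrobial lectin Reg3g (2021 ± 1635 against 929 ± 739 CPM, 1.12) pointed in opposite directions and did not pass. Hepatocyte transcripts were present in the same libraries (Alb at 86.9 ± 45.9 against 125 ± 43.9 CPM), and the cell source of Saa1 and Saa2 was not tested. Il22 had 0 counts in all 28 libraries, which allows up to 0.0627 CPM in Lgr5-high cystine cells and 0.0289 CPM in Lgr5-high control cells at 3 counts per group. Il22ra1, a subunit of its receptor, had 13, 2, 10 and 2 counts in the Lgr5-high control, Lgr5-high cystine, Lgr5-low control and Lgr5-low cystine groups and was too low to test. Cell cycle (median 0.03), Wnt target (-0.07), cysteine transport and catabolism (-0.15), glutathione and NRF2 (0.02) and coenzyme A metabolism genes (0.00) did not pass, with adjusted p = 0.959, 0.959, 0.671, 0.959 and 0.911. Cysteine transport and catabolism genes passed as lower without the libraries under 5 M counts (adjusted p = 0.0424).

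**Figure D3:**
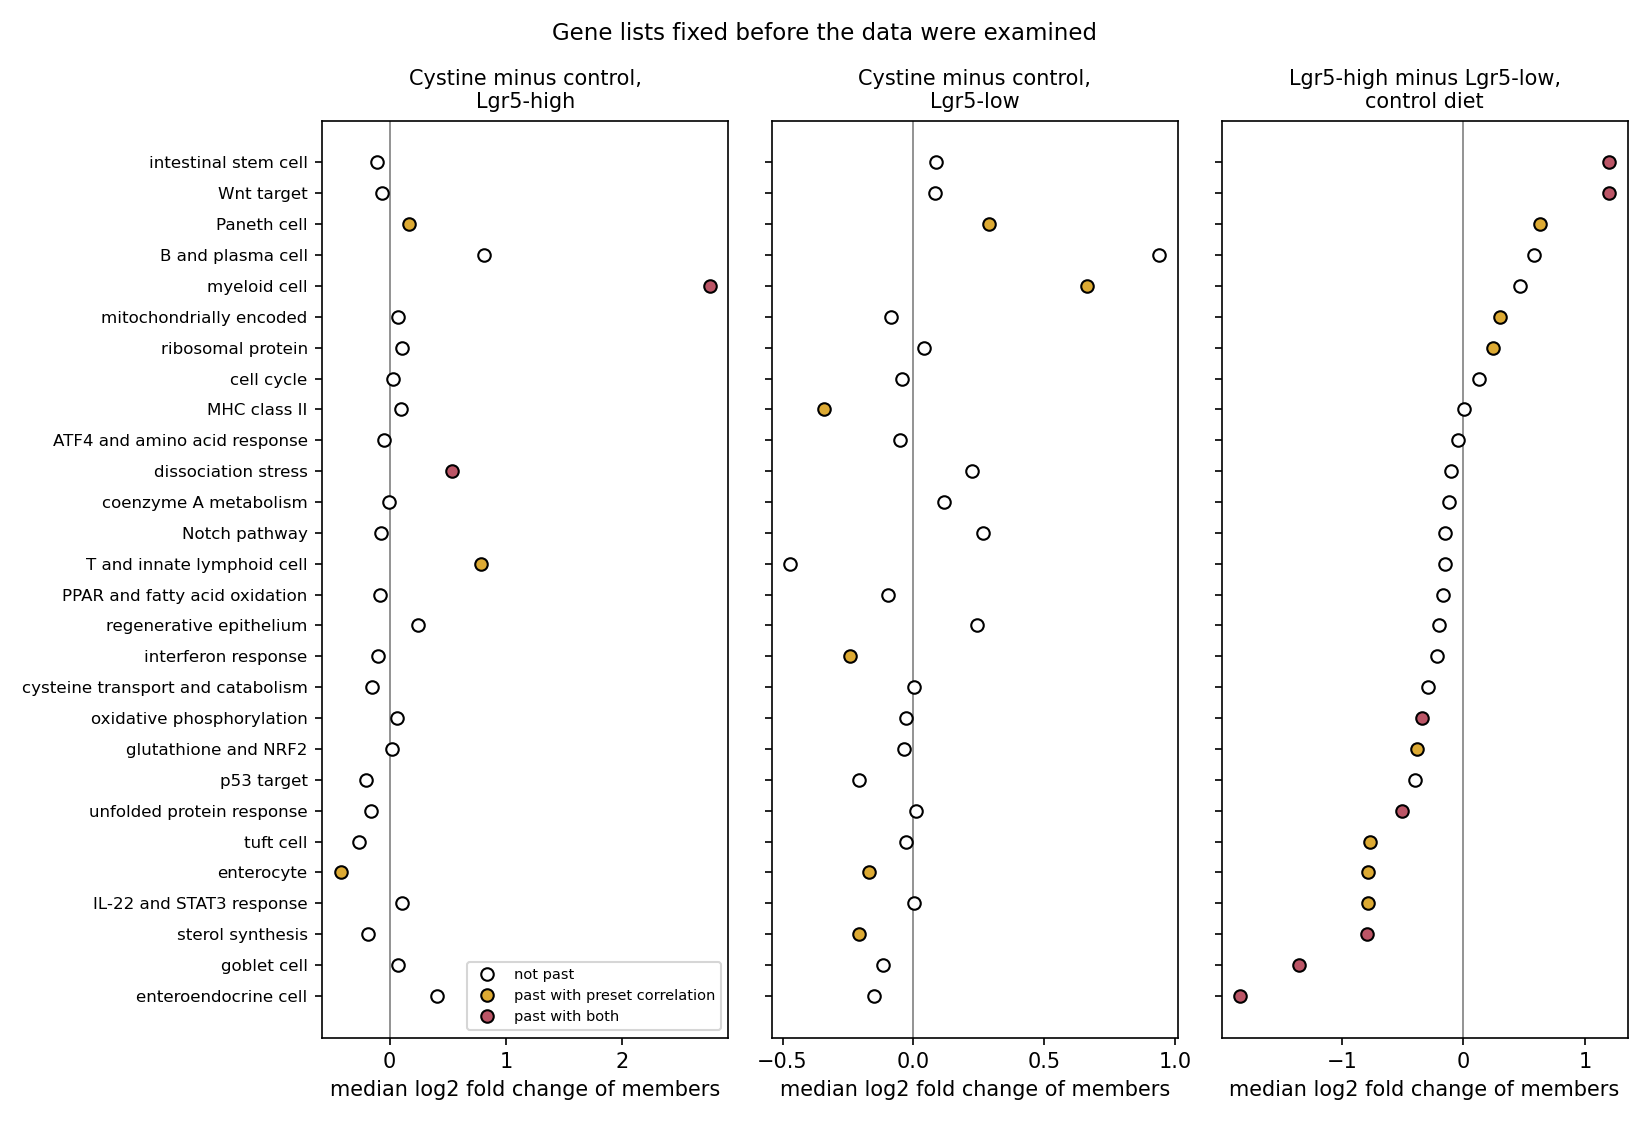
Median log2 fold change of the tested members of the 29 tested gene lists except the sex-linked list, which is not drawn. Panels show the cystine diet in Lgr5-high and in Lgr5-low cells and Lgr5-high against Lgr5-low cells on control diet (linear axes of different range). White points did not pass, yellow points passed with the preset correlation only and red points with both; in the Lgr5-high diet panel the myeloid list lies at 2.75 and the intestinal stem cell list at -0.11.

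In Lgr5-low cells no gene passed between the diets in edgeR. Retnlb, a resistin-like molecule secreted by goblet cells, had 215 counts in 6 of 7 cystine libraries and 2 counts in 1 of 7 control libraries, a ratio of depth-scaled sums of 67.4 (exact 95% interval 18.4 to 560, counting error only). Cystine replicate 1 held 72 of these counts at 20.7 CPM, where the other 6 libraries held 0 to 3.92 CPM, and without it the ratio was 46.9 (12.7 to 391). Retnlb reached an adjusted p of 1.0 over all genes and 0.0142 adjusted over the interleukin 22 and STAT3 response list alone. That list did not pass in Lgr5-low cells, with a median log2 fold change of 0.002 and 7 of 13 tested members positive. Its camera adjusted p was 0.340, and 0.895 with an estimated correlation. Reg3b and Reg3g, lectins that act against bacteria, measured 7025 ± 5274 against 2212 ± 1849 CPM (SD, n = 7; log2 fold change 1.67 ± 0.70 SE) and 3677 ± 2526 against 1422 ± 1080 CPM (1.37 ± 0.63), with 6 of 7 cystine libraries above the control median in each, and neither passed. Lgr5 stood at 6.76 ± 2.89 against 4.19 ± 3.61 CPM (0.60 ± 0.42), and the stem cell list had a median of 0.09 (adjusted p = 0.140).

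In edgeR 0 genes passed, and 371 had an unadjusted p under 0.05 where chance would give 625. With DESeq2 4 genes passed, 9230105E05Rik, 9530080O11Rik, Garnl3 (2.07 ± 0.936 against 6.80 ± 1.39 CPM, adjusted p = 0.00993) and Osr2 (0.0204), and with limma-voom 1, the metallothionein gene Mt2 (63.5 ± 26.3 against 15.6 ± 13.5 CPM, log2 fold change 3.83 in limma-voom and 2.07 in edgeR, adjusted p = 0.00532 and 1.0). The other genes of lowest p under the naming rule were, with positive values, Cabcoco1 (12.1 ± 6.33 against 4.03 ± 2.09 CPM), the insulin-degrading protease Ide (21.1 ± 6.80 against 10.8 ± 2.76 CPM) and Mterf3, a regulator of mitochondrial transcription (15.9 ± 7.75 against 7.56 ± 2.77 CPM). With negative values they were ccdc198, Ofd1 and Dhrs7 (76.7 ± 9.48 against 111 ± 21.2 CPM), and none of these passed. Within the female class 0 genes passed in edgeR (1079 with an unadjusted p under 0.05) and within the male class 3, Sprr2a2, Sult6b2 and Sectm1b, named after their values were seen.

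Of the lists 6 passed in Lgr5-low cells with the preset correlation, all with an adjusted p of 0.895 with an estimated correlation. Lower on cystine were enterocyte (median -0.17, adjusted p = 0.00183), interferon response (-0.24, 0.0159), MHC class II (-0.34, 0.0234) and sterol synthesis genes (-0.21, 0.0407), and higher were Paneth cell (0.29, 0.0159) and myeloid genes (0.66, 0.0159). In these lists 0 members passed adjusted over the list alone. Examples were Irgm1, an interferon-induced GTPase (34.5 ± 12.1 against 50 ± 22.9 CPM), H2-Ab1, a chain of the MHC class II molecule (28.7 ± 18.7 against 45.4 ± 22.7 CPM), and Mptx2, a Paneth cell pentraxin (1475 ± 562 against 782 ± 652 CPM). Without the libraries under 5 M counts the enterocyte, interferon, MHC class II, sterol and Paneth calls ended (adjusted p = 0.157, 0.122, 0.207, 0.145 and 0.0679). Lists past the threshold numbered 1 within the female and 2 within the male class.

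The last comparison tested whether the diet effect differed between the populations. The gene with the lowest p among named positive values was Clta, a clathrin light chain (difference of log2 fold changes 1.11 ± 0.27 SE, adjusted p = 0.558), followed by Cd68 (2.38 ± 0.61, 0.726), Fcer1g (2.04 ± 0.59), Tyrobp (2.52 ± 0.72) and the proteoglycan Srgn (3.11 ± 0.95). The lowest p among named negative values belonged to Rgcc (-2.10 ± 0.57), the acute-phase protein Orm1 (-2.27 ± 0.64), the glutathione transferase Gstt1 (-0.97 ± 0.29), Fam98b (-1.26 ± 0.39) and Cabcoco1 (-1.58 ± 0.50). In edgeR 0 genes passed (415 with an unadjusted p under 0.05), with DESeq2 0 and with limma-voom 6. Of the lists, myeloid genes had a larger diet effect in Lgr5-high cells (median difference 1.95, adjusted p = 4.04e-12, but 0.194 with an estimated correlation), with 0 of 10 members past the threshold over all genes and 5 adjusted over the list alone. T and innate lymphoid genes also had a larger effect there (0.97, adjusted p = 0.0304, but 0.964 with an estimated correlation; 0.0562 with RLE size factors). The myeloid difference had an adjusted p of 2.52e-14 in the female class and 0.639 in the male class, and 3 and 0 genes passed in these classes in edgeR (820 in the male class had an unadjusted p under 0.05). The 3 were Gm9493, H2aj and Eef2, named after their values were seen. For Lgr5 the difference was -1.03 ± 0.58.

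Across the 12495 tested genes, which are not independent replicates, the diet effects in the populations correlated with Pearson r = 0.10 and Spearman rho = 0.06. When diet labels were permuted jointly in both populations, the median r was 0.06 and the range -0.03 to 0.24 (permutation p = 0.25 from 99 permutations). The effects were thus not shown to be shared beyond what regrouping the same libraries gives.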

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

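All tests of explanations in this part were chosen after the results had been seen, except the other splits of the libraries, which were planned.

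Macrophage transcripts were higher on cystine in Lgr5-high cells, the markers include genes of liver macrophages, and liver sinusoidal endothelial genes had log2 fold changes as large without passing (Dnase1l3 3.81, adjusted p = 0.0517; Fcgr2b 3.10, 0.146; Clec4g 2.76, 0.0934). Whether macrophages of the intestine alone were the source was not settled, because the markers were chosen after the results. Clec4f, Vsig4 and Cd5l, used as liver markers, are among the 21 called genes, so their high values were given in advance. Over the cystine libraries the median of Clec4f, Vsig4, Cd5l and Timd4 was 30.9 CPM. It lay above that of the intestinal genes Cx3cr1, Ccr2, Itgax and Cd209a (0) in 7 of 7. Mrc1, the one intestinal marker abundant enough to test, had a log2 fold change of 2.42 (adjusted p = 0.597). The hepatocyte genes argue against a rise of all liver RNA by as much as the macrophage genes. The 8 hepatocyte genes had log2 fold changes from -0.53 to 0.50 (median -0.25, median SE 0.363). The lowest of the 8 genes of the macrophage score was 2.57. Of these 8, Clec4f, Vsig4, Cd5l, Folr2 and C1qb are called genes, so the size of that gap was in part given in advance. A fixed amount of macrophage RNA or reads, the same in libraries of both diets and made visible by low depth, was not settled: 6 of 7 cystine libraries held 735 to 1535 macrophage counts, above all control libraries (97 to 719), but replicate 1 held 79 and lay below all of them (log2 difference of counts 1.01, exact permutation p = 0.152, and 0.0262 on ranks). Depth alone would give a log2 fold change of 1.27 where the markers had a median of 2.84 (largest SE 1.02), and sample handling was not tested. In Lgr5-high cystine libraries the slope of log2 macrophage counts on log2 total counts was -1.03, and -0.02 (SE 0.24) without replicate 1. In the Lgr5-high control, Lgr5-low control and Lgr5-low cystine groups it was 0.99, -0.12 and 0.37, and 0.34, -0.08 and -0.19 without replicate 1. A constant share would give 1 and a constant amount 0. The slopes hinge on replicate 1 and did not settle the source.

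Dissociation stress genes were higher in the same libraries. A source shared with the macrophage transcripts remains possible, as the ranks of the means of both gene sets were identical across the 7 cystine libraries (Spearman rho = 1, exact p = 0.000397, adjusted 0.00159 over 4 relations). In the other groups rho was 0.32, 0.14 and -0.50 (p = 0.498, 0.783 and 0.267). A response of the stem cells themselves was not tested, and bulk counts cannot separate it.

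Between the male and female classes 2132 genes differed, 1003 higher and 1129 lower in the male class. Genes of the sex chromosomes alone were excluded as the cause, with 3.24% of these genes on X or Y against 2.93% of tested genes. A bias with transcript length remains possible: log2 fold changes correlated with exon length at Spearman rho = -0.30 over 12095 genes that are not independent, against -0.10, 0.01, 0.01 and -0.06 in the 4 diet and population contrasts. The median exon length was 2253 bases among genes higher in the male class and 6435 among those lower. Separate collection or library batches may coincide with the classes, because replicate numbers run in parallel with them, and the labels name no batch.

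Among 100 splits of the libraries, the real one included, 1 had as many calls as the diet effect in Lgr5-high (21 real, 1 the highest other). For the diet effect in Lgr5-low it was 100 (0 real, 520 the highest other), and in the 4 splits with over 100 calls all males stood on one side. For the difference of diet effects it was 100 (0 real, 0 the highest other). With 0 real calls every split has as many, so the 100 was fixed in advance in both cases and says nothing about chance. For the populations the number of splits was 1 on control diet (225 real, 3 the highest other) and 1 on cystine diet (330 real, 173 the highest other). Among 75 splits for the lists, the numbers with as many lists were 61 (5 real, 14 the highest other), 35 (6 and 14), 61 (2 and 14), 4 (14 and 16) and 4 (15 and 16) in the same order. For none of the 5 contrasts can chance therefore be excluded as a source of the number of lists past the threshold with the preset correlation. The male and female classes differ in such lists themselves, but among splits with the classes as balanced as in the real one, 42 of 54, 22 of 51, 39 of 49, 3 of 36 and 3 of 24 still had as many lists (highest other 14, 14, 14, 16 and 16; this restriction was chosen after the results were seen). With an estimated correlation the numbers were 3, 75, 75, 1 and 2, where each 75 was fixed by the 0 real lists of its contrast.

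Of 68 tests for an extreme library in a group (17 measures), 8 exceeded the critical value, where 3.4 would by chance. Lgr5-high control replicate 1 had a log2 total of 21.95 (others 23.64 to 24.35) and 11880 detected genes (others 14635 to 16052). Lgr5-low cystine replicate 1 had a mitochondrially encoded share of 19.2% (others 14.2% to 15.7%) and a log2 CPM of Mt1 of 10.63 (others 9.55 to 10). Lgr5-low cystine replicate 7 had a log2 CPM of Mt2 of 4.23 (others 5.69 to 6.73). Lgr5-high cystine replicate 1 had a macrophage score of -0.37 (others 3.29 to 5.15), a log2 CPM of Cd68 of 2.44 (others 4.98 to 6.61) and a log2 CPM of Chgb of 4.11 (others 5.52 to 5.89). All libraries were kept. The diet effect differed between populations for the myeloid list (adjusted p = 4.04e-12) and the T and innate lymphoid list (0.0304), and neither passed with an estimated correlation.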

How the results depend on the processing

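The sex term, the macrophage score term, the limit on depth and leaving out single libraries were chosen after the results had been seen. The cause of these changes was not tested.

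For the diet effect in Lgr5-high (21 genes) the count was 89 with DESeq2, 38 with limma-voom, 39 with only the compared groups, 41 with a sex term, 1 with a macrophage score term and 0 without libraries under 5 M counts. Leaving out single libraries gave 7 (without control replicate 7) to 44 (without cystine replicate 1). For the diet effect in Lgr5-low (0) it was 4 with DESeq2 and 1 with limma-voom. For the difference of diet effects (0) it was 6 with limma-voom, 1 with a macrophage score term, 1 without libraries under 5 M counts, and 0 to 2 with single libraries left out (2 without Lgr5-low cystine replicate 1).

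For the populations on control diet (225) the count was 410 with DESeq2, 781 with limma-voom, 144 with no low-count filter, 131 with only the compared groups, 409 with a replicate term and 450 with a sex term. Leaving out single libraries gave 123 (without Lgr5-high replicate 5) to 464 (without Lgr5-low replicate 3). On cystine diet (330) it was 585 with DESeq2, 880 with limma-voom and 619 with a sex term, and 183 (without Lgr5-low replicate 7) to 396 (without Lgr5-low replicate 1) with single libraries left out.

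The lists past the threshold (5, 6, 2, 14 and 15) numbered 2, 0, 0, 7 and 7 with an estimated correlation. For the diet effect in Lgr5-high they were 8 with a macrophage score term and 9 without libraries under 5 M counts, and in Lgr5-low 2 without those libraries. For the difference of diet effects they were 1 with RLE size factors, 4 with a replicate term and 5 without those libraries.

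With the macrophage score term, built from 8 genes that include Vsig4 and C1qb, the diet effect in Lgr5-high turned in Vsig4 (-0.19), Aif1 (-0.32) and C1qb (-0.26). For Vsig4 and C1qb this followed in part from the construction of the score. Without libraries under 5 M counts, 22 of 143 results for named genes were weaker. The labels do not say whether same-numbered libraries share an animal, and the values did not settle it. For each gene the mean log2 CPM of the group was first subtracted, so the correlations concern deviations from the group mean and not whole profiles. Those of same-numbered libraries ranged from -0.05 to 0.11 between the Lgr5-high diets, from 0.07 to 0.24 between the populations on control diet (4 of 7 over 0.1, and 4 of 7 highest with their own number) and from -0.08 to 0.17 on cystine diet (1 and 3 of 7). Between the Lgr5-low diets the correlations ranged from -0.09 to 0.12 (3 of 7 over 0.1, and 3 of 7 highest with their own number). The male and female classes of same-numbered libraries matched between the populations in 7 of 7 pairs on each diet. They also matched in 6 of 7 pairs between the diets in each population, so the match does not single out pairing. Not all correlations exceeded 0.1, so the replicate term was not read as a pairing.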

Other observations

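The metallothionein genes and the readings in this part were chosen after their values had been seen.

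Metallothioneins, cysteine-rich proteins that bind metals, had higher means on cystine in both populations and did not pass in edgeR over all libraries without further terms. Within the male class (2 cystine against 3 control libraries) Mt1 and Mt2 passed in Lgr5-high cells (log2 fold change 1.19 and 2.82, adjusted p = 0.0211 and 0.00055). In the female class neither did (0.131 and 0.677), and in Lgr5-low cells neither passed in either class. In Lgr5-high cells Mt1 measured 1386 ± 430 CPM on cystine against 693 ± 178 on control diet (SD, n = 7; log2 fold change 1.0 ± 0.24 SE, adjusted p = 0.0773, and 0.00261 with a sex term). In Lgr5-low cells it measured 956 ± 294 against 542 ± 254 CPM (0.82, adjusted p = 0.0949 with a sex term). Mt2 had log2 fold changes of 2.3 (adjusted p = 0.136) in Lgr5-high and 2.07 (adjusted p = 1.0) in Lgr5-low cells; in the latter it passed with limma-voom, at a log2 fold change of 3.83 (adjusted p = 0.00532).

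The sorted populations differed in the same direction on both diets, which rests on separate libraries, and this is the firmest result. For the diet, the genes that passed were mostly macrophage genes, and the stem cell and interleukin 22 response lists did not pass. The common coefficient of variation was 0.629, and 26% of changes by a factor of 2 were recovered in simulation, among genes of at least 2 CPM. A moderate change of stem cell genes in Lgr5-high cells was thus not ruled out. The stem cell list had a median log2 fold change of -0.11, and how large a shared shift would have passed with an estimated correlation was not tested.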
